A study of Mus musculus with 5 samples.

How the data were processed

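WT1 binding was profiled by CUT&RUN, an assay in which an antibody held on chromatin inside permeabilised cells recruits a protein A-micrococcal nuclease fusion, so that DNA next to the bound protein is cut out and sequenced. The series holds 5 samples of the mouse line M15. WT1 antibody libraries came from M15 cells (2 replicates) and from a derived line that the labels call KTS-minus (2 replicates), and 1 library was made from M15 cells with an IgG control antibody. A peak list was used for each of the 4 WT1 libraries. The IgG library was not analysed here. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical.

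Per the submitters' processing notes, the tools were FastQC 0.11.8, Bowtie2 2.2.6, Picard 2.5.0, SAMtools 1.3, bedtools 2.23.0 and SEACR 1.3, and the genome build was mm9. SEACR calls a peak from a continuous stretch of coverage whose summed height passes a threshold. The lists were made per library, not on pooled replicates, and their names carry the suffix of SEACR's stringent mode. The deposited lists have 6 columns: chromosome, start, end, total signal, max signal and the stretch that reaches the max signal. In all 4 lists the deposited signal values were whole numbers, and a peak's signal is the authors' own coverage value. Whether coverage was scaled between libraries, which control or numeric threshold entered the peak calling, and how the yeast spike-in DNA named in the labels' protocols was used are not given in the sources used here. Signal values were therefore used only to describe, rank or filter peaks inside a list. Read depth is unknown, because the lists hold no read counts. Intervals on shares are 95% Wilson intervals over peaks and cover counting error only. Neighbouring peaks are not independent, and peaks are not replicates.

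Coordinates are mm9, counted from 1. The last peak on chromosome 1 ended at 197194788, past the last gene end of 195291439 on that chromosome in the gene table at hand, which belongs to the later assembly GRCm38. No coordinate of that table was used, and peaks were not assigned to genes, promoters, exons or sequence motifs. The planned analyses of promoter share, WT1 motif share and gene lists were therefore not run.

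Peaks of the 4 lists were merged into regions where they shared at least 1 bp. A region was called reproducible in a line when both replicates of that line had a peak in it. For comparisons at equal length, each list was reduced to its 6440 peaks with the highest max signal, the length of the shortest list, with ties broken by total signal. The similarity of 2 such lists is the share of peaks overlapped by at least 1 bp, averaged over both directions. Chance overlap was measured by moving peaks. In a circular shift, a list is rotated by a random distance along each chromosome. In a local shift, it is moved by 20 to 100 kb, which keeps the peaks in their own neighbourhood. The main region counts were set against 1000 circular shifts, pairs of lists and local shifts against 100 unless stated otherwise, and quartiles of M15 peaks against 20 local shifts. One-sided p-values are the share of shifts, the observed value included, that reached the observed value. These tests ask whether lists overlap beyond random placement. They do not test a difference between the lines: with 2 libraries against 2, an exact permutation test cannot go below p = 0.333, so no such test is reported. Chromosome 13 and the other chromosomes were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 20 chromosomes.

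Peaks were also counted in 1 Mb bins. Dense blocks were runs of at least 3 bins in which the summed signal was at least 4 times the library's median bin in at least 3 libraries. A library's median bin was taken over the bins that held a peak in that library. This definition, the local shift, the quartiles, the strength of KTS-minus peaks at M15 regions, the correlation of bins and the comparison by chromosome of M15 regions missing from KTS-minus lists were chosen after the data had been examined. Groups, comparisons, the alternatives named as planned and the rule for named regions were fixed before the data were examined. That rule takes 6 regions per class, ordered by mean rank of max signal inside the lists: (a) regions with a peak in all 4 libraries, (b) regions with a peak in both M15 libraries and neither KTS-minus library, and (c) regions with a peak in both KTS-minus libraries, in the equal-length list of each, and in neither M15 library. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. On simulated lists with a known shared set of 2997 sites, the merging step returned 2997 shared regions. The simulated sites were sparse and could not merge with their neighbours, so this checks the code only. It says nothing about merging in lists as dense as those of KTS-minus.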

Results

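WT1 is a zinc-finger transcription factor of the developing kidney and gonad. Alternative splicing adds or leaves out the amino acids lysine, threonine and serine (KTS) between its last zinc fingers, and the KTS-lacking form is the one best known as a sequence-specific DNA binder. M15 is a mouse mesonephric epithelial line transformed with polyoma virus large T. The series compared WT1 occupancy in M15 cells with that in an M15 line edited for the KTS isoforms and named KTS-minus in the labels, which do not spell out which isoform the edited cells still make.

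The 4 WT1 peak lists differed widely in length. M15 replicate 1 listed 6440 peaks covering 12.3 Mb, and M15 replicate 2 listed 60925 peaks covering 71.9 Mb. KTS-minus replicate 1 listed 310999 peaks covering 434.1 Mb, and KTS-minus replicate 2 listed 244428 peaks covering 199.5 Mb. The mean was 33682.5 ± 38526.7 peaks (SD, n = 2) in M15 and 277714 ± 47073 (SD, n = 2) in KTS-minus, a ratio of 8.25. Both KTS-minus lists were longer than both M15 lists, but the M15 replicates themselves differed 9.46-fold. The lists also differed in peak shape: the median width was 1673 bp and 1009 bp in M15 replicates 1 and 2, and 1108 bp and 684 bp in KTS-minus replicates 1 and 2. Median max signal, in each list's own coverage units, was 35 and 7 in the M15 lists and 13 and 21 in the KTS-minus lists.

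**Figure D1:**
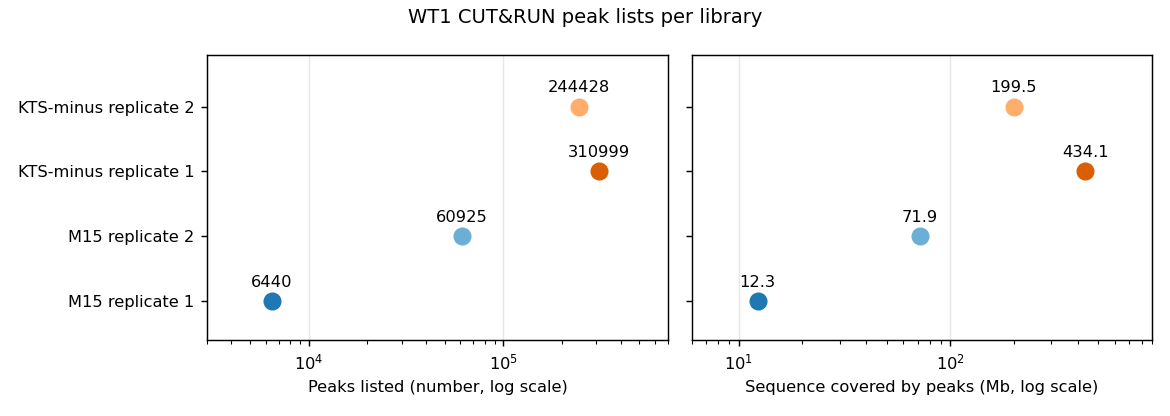
Number of listed peaks (left, log axis) and sequence covered by them in Mb (right, log axis), with 1 point per WT1 library. KTS-minus libraries list 244428 and 310999 peaks against 6440 and 60925 in M15.

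The first comparison asked which M15 sites were found in both replicates. M15 replicate 1, the shorter list, was almost contained in replicate 2: 95.5% of its peaks (95% interval 94.9 to 96.0) overlapped a replicate 2 peak, against 8.83% ± 0.70 (SD over 100 circular shifts) and 21.9% ± 1.33 (SD) after local shifts. In the opposite direction 10.9% of the replicate 2 peaks overlapped replicate 1. After merging, 5688 regions were reproducible in M15, against 828 ± 53.0 (SD) over 1000 circular shifts, a ratio of 6.87 (one-sided permutation by shifts, p = 0.001, the smallest they can give). The KTS-minus libraries shared 83328 regions, 14.6 times as many as the M15 libraries, and 5.49 or 4.57 times as many when a 50% reciprocal overlap was asked or only the stretches of highest signal were overlapped. Random placement alone gave 70506 ± 460 (SD) shared KTS-minus regions, so the observed number was 1.18 times the number by chance (the same permutation, p = 0.001, again the smallest possible). Only 28.8% of KTS-minus replicate 1 peaks overlapped replicate 2, against 26.1% ± 0.15 (SD) after local shifts, and 42.6% of replicate 2 peaks overlapped replicate 1, against 38.0% ± 0.29 (SD).

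The second comparison asked whether the M15 sites were also occupied in the edited line. Of the 5688 reproducible M15 regions, 5331 (93.7%, 95% interval 93.1 to 94.3) held a peak in both KTS-minus libraries, 287 (5.05%) in 1 of them and 70 (1.23%) in neither. The share was 95.9% in KTS-minus replicate 1 and 96.6% in replicate 2. Circular shifts of the M15 peaks gave 23.4% ± 0.85 (SD) with both KTS-minus libraries (one-sided permutation, p = 0.001, the smallest 1000 shifts can give), and local shifts gave 37.0% ± 1.3 (SD). The observed share was 4.00 and 2.53 times these values. Overlap rose with the strength of the M15 peak. Among all M15 replicate 2 peaks, 23.5% of the quartile with the lowest max signal lay in both KTS-minus lists, against 19.1% after local shifts, and 73.4% of the quartile with the highest max signal did, against 33.6%. The share therefore depends on which M15 sites are taken: M15 replicate 1 alone gave 91.7%, and replicate 2 alone, the longer list, gave 42.3%. It also depends on overlapping whole peaks. When only the stretches of highest signal were overlapped, 1869 M15 regions were reproducible. Of those, 24.1% coincided with such a stretch in both KTS-minus libraries, against 2.5% ± 0.40 (SD) after local shifts.

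**Figure D2:**
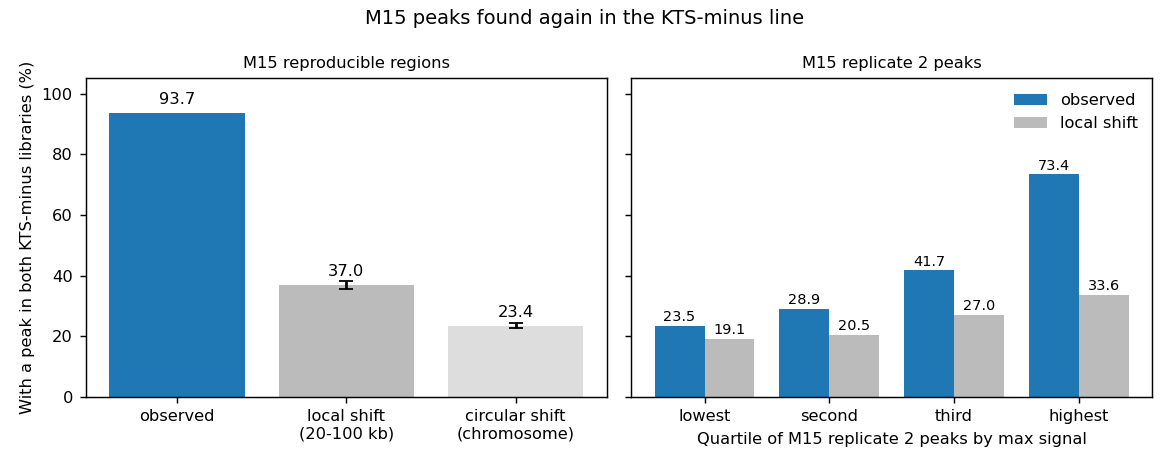
Share of M15 regions (left) and of M15 replicate 2 peaks by quartile of max signal (right) with a peak in both KTS-minus libraries, in percent, beside shifted positions; error bars are the SD over shifts. The observed share is 93.7% against 37.0% and 23.4% after shifts, and climbs from 23.5% to 73.4% with M15 signal.

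KTS-minus peaks at reproducible M15 regions were stronger and wider than KTS-minus peaks elsewhere. In KTS-minus replicate 1 the 7294 peaks at reproducible M15 regions had a median max signal of 20, against 13 for the 303705 peaks elsewhere. In replicate 2 the medians were 29 for 10866 peaks and 20 for 233562 peaks. The 6440 strongest peaks held 30.0% of the peaks at M15 regions but 1.40% of the others in replicate 1, and 25.2% and 1.58% in replicate 2. Median width was 2418.5 bp against 1099 bp in replicate 1 and 1187 bp against 673 bp in replicate 2, and wide peaks meet an M15 region more often by chance. KTS-minus peaks met by locally shifted M15 regions, which favours wide peaks too, had median widths of 1505 bp and 895 bp, and 9.59% ± 0.55 and 11.5% ± 0.44 (SD over 100 shifts) of them were among the 6440 strongest in replicates 1 and 2.

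The regions with the best mean rank over all 4 libraries lay on 6 different chromosomes. The first, on chromosome 17 from 71312317 to 71313255, had a max signal of 206 and 122 in M15 replicates 1 and 2 and of 223 and 268 in KTS-minus replicates 1 and 2. The region on chromosome 12 from 79451243 to 79452399 reached 179 and 104 in M15 and 222 and 284 in KTS-minus. The region on chromosome 5 from 147071547 to 147073468 reached 160 and 107 in M15 and 306 and 374 in KTS-minus. The region on chromosome 6 from 3150645 to 3153937 reached 168 and 82 in M15 and 217 and 246 in KTS-minus. The last of the 6 were on chromosome 10 from 127097162 to 127108660 (223 and 90 in M15, 101 and 167 in KTS-minus) and on chromosome X from 133273798 to 133287895 (214 and 87 in M15, 89 and 209 in KTS-minus). The chromosome 10 region lies inside the dense block from 118000001 to 128000000 described below. Values of different libraries have no common scale and give no change between lines. Genes at these positions were not assigned here.

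M15 regions without a KTS-minus peak numbered 70. The top-ranked was a stretch of 55343 bp on chromosome 10 from 126465971 to 126521313, with a max signal of 203 and 36 in the M15 replicates. A second chromosome 10 stretch ran from 126631296 to 126669964 (56 and 21). Both stretches lie inside the dense block from 118000001 to 128000000 described below. Peaks covered 83.4% and 54.4% of that block in KTS-minus replicates 1 and 2, so these stretches are gaps in a densely covered segment. From these stretches the nearest KTS-minus peaks were 21013 bp and 45460 bp away in replicate 1 and 7322 bp and 2211 bp away in replicate 2. The other named regions were on chromosome 8 from 129442583 to 129444151 (62 and 30), chromosome 4 from 136715179 to 136718007 (73 and 23), chromosome 15 from 85864316 to 85865599 (60 and 25) and chromosome 6 from 91526056 to 91527747 (43 and 26). Of all 70 regions, 30 (42.9%) had a KTS-minus peak within 1 kb. The same regions were also moved by 1000 local shifts, keeping positions that held no KTS-minus peak, a choice made after seeing the data. This was possible for 68 regions and gave an expected number of 24.0. The observed number lay less than 2 SD above it, with a binomial SD of 3.43. That SD takes the regions as independent and is not the spread over shifts. By chromosome, the missing regions were most frequent on chromosome 13, where 14 of 214 reproducible M15 regions (6.54%) had no KTS-minus peak, against 1.02% on all other chromosomes (Fisher's exact test, adjusted p = 4.4e-06). Chromosome 12, with 6 of 104, and chromosome 1, with 7 of 184, also passed (Fisher's exact test, adjusted p = 0.016 and 0.047). The test takes no account of peak density: KTS-minus replicate 1 listed 48.4, 36.2 and 54.4 peaks per Mb on chromosomes 13, 12 and 1, against 221, 245 and 248 on chromosomes 15, 6 and 19, where 0.26%, 0.50% and 0 of the M15 regions had no KTS-minus peak. Chromosome 7, with 44.0 peaks per Mb, had 0.94% without one, and chromosome 3, with 44.1, had 2.19%. KTS-minus replicate 2 listed 64.9 peaks per Mb on chromosome 13, more than on chromosomes 12, 1, 3 and 7 (30.9, 41.0, 39.4 and 34.6). Peak density alone therefore does not order the chromosomes by their missing share.

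KTS-minus regions without any M15 peak numbered 61442, or 73.7% of the reproducible KTS-minus regions. In 44 of them both KTS-minus libraries had a peak among their 6440 strongest. That cut kept 1.40% and 1.58% of the peaks away from reproducible M15 regions in KTS-minus replicates 1 and 2. The number 44 therefore depends on the cut, and the number expected by chance was not computed. The highest-ranked was on chromosome 10 from 117225399 to 117232103, with a max signal of 52 and 58 in KTS-minus replicates 1 and 2. It was followed by regions on chromosome 8 from 14289253 to 14289986 (34 and 53), chromosome 18 from 14261623 to 14262085 (54 and 47), chromosome 1 from 188284566 to 188286611 (32 and 54), chromosome 6 from 12759325 to 12765247 (29 and 63) and chromosome 1 from 93146435 to 93146939 (31 and 49). In each KTS-minus library these max signals were lower than at the 6 named regions found in all 4 libraries. Both sets were picked by rank of max signal, from 44 and 5331 regions respectively. The larger pool favours higher values, so this order does not show that regions without an M15 peak are weaker.

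At equal list length the M15 replicates resembled each other most. Their 6440 strongest peaks overlapped at 66.5%. The KTS-minus replicates overlapped at 33.3%, and the 4 pairs of libraries from different lines at 34.5% to 41.1% (mean 38.2% ± 2.74, SD). Circular shifts gave means of 1.1% to 2.3%. The mean within lines exceeded the mean between lines by 11.7 percentage points, but this depended on the M15 pair. Without M15 replicate 2 the difference was -3.35, and without M15 replicate 1 it was -6.58 at the same list length and -3.70 with lists of 60925 peaks, the shortest then left. The place of the KTS-minus pair depended on the ranking: by total signal it overlapped at 55.6%, above every pair between lines (36.1% to 53.8%), and the M15 pair at 60.5%. The 4 libraries can be split into pairs in only 3 ways, so the difference was not tested. After merging, 1275 of 14667 regions were present in all 4 equal-length lists, and 63.1% were in 1 list only. Regions in both M15 lists and neither KTS-minus list numbered 1551, and regions in both KTS-minus lists and neither M15 list 291. The pairs made of 1 library from each line gave 122 to 251 such regions.

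**Figure D3:**
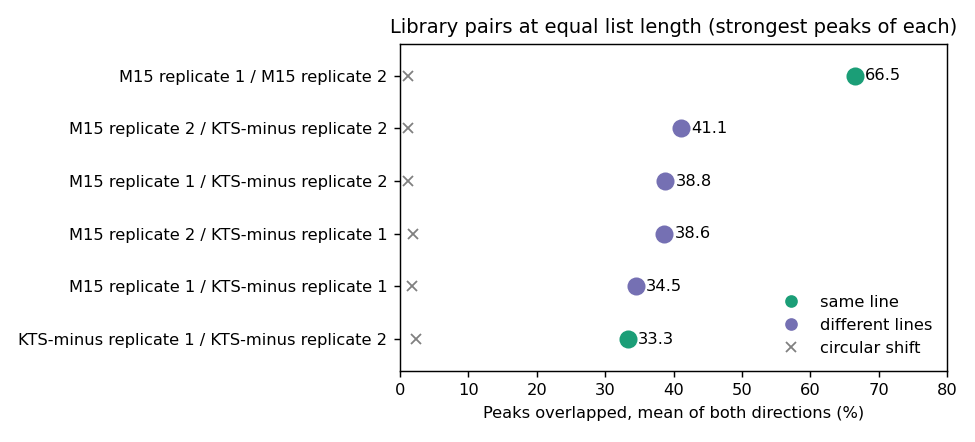
Overlap of the 6440 strongest peaks for each pair of libraries, in percent of peaks averaged over both directions; crosses mark the mean of circular shifts. The M15 pair stands at 66.5%, while the KTS-minus pair (33.3%) lies below the pairs of different lines (34.5% to 41.1%) in this ranking by max signal and above them (55.6% against 36.1% to 53.8%) when ranked by total signal.

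The lists of the lines also differed in how their strongest peaks were spread over chromosomes. DNA copy number was not measured. A different number of copies of a chromosome, or of a part of it, therefore cannot be told apart from a different spread of WT1. On chromosome 6 the equal-length lists held 11.96% ± 2.55 (SD, n = 2) of the KTS-minus peaks and 7.17% ± 0.38 (SD, n = 2) of the M15 peaks, a ratio of 1.67. On chromosome X the shares were 12.2% ± 0.68 and 5.56% ± 3.38 (SD, n = 2 each), a ratio of 2.2, with a wide gap between M15 replicate 1 (3.17%) and replicate 2 (7.95%). In whole lists the chromosome X ratio was 1.07, and M15 replicate 2 (11.6%) lay above both KTS-minus libraries (6.59% and 9.20%). Chromosome 7 held 2.22% ± 0.29 in KTS-minus and 3.39% ± 0.32 in M15, and chromosome 13 held 2.28% ± 0.78 and 3.47% ± 0.10 (SD, n = 2 each), ratios of 0.65 and 0.66. Ranked by total signal, the ratios were 0.34 and 0.40. Both KTS-minus libraries lay above both M15 libraries on 3 of 20 chromosomes (6, 10 and X) and below both on 8. Chance order alone would give 3.33 chromosomes in each direction, but shares sum to 100%, so that higher shares on some chromosomes lower the others. With chromosomes 6, 10 and X left out and shares scaled again, a choice made after seeing the data, both KTS-minus libraries were below both M15 libraries on 6 of 17 chromosomes, 7 and 13 among them, and above both on 5, against 2.83 by chance order. Among the chromosomes on which the lines did not overlap at equal length, the direction in whole lists was opposite for chromosome 10 (1.31 at equal list length, 0.67 in whole lists), chromosome 4 (0.87 and 1.09) and chromosome 12 (0.74 and 1.10). It also turned on chromosomes 1, 3, 9, 15, 18 and 19, where the lines overlapped.

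The sequence covered by peaks changed in large steps along some chromosomes. On chromosome 10 from 118000001 to 128000000, peaks covered 83.4% of the sequence in KTS-minus replicate 1 and 54.4% in replicate 2, against 15.8% and 7.09% outside dense blocks. In M15 the same block was covered to 8.15% and 26.8% in replicates 1 and 2, against 0.42% and 2.41%. Mean coverage inside its peaks was 10.4 and 11.4 in the KTS-minus lists, against 5.33 and 8.65 inside other peaks, and 9.05 and 4.75 in the M15 lists, against 11.3 and 3.65. On chromosome X, the blocks from 12000001 to 20000000, 82000001 to 85000000 and 154000001 to 167000000 together were covered to 67.0% and 47.1% in KTS-minus and to 24.3% in M15 replicate 2. In M15 replicate 1 they were covered to 1.16%, against 0.42% elsewhere, and the block from 82000001 to 85000000 alone to 2.94%. On chromosome 7, no peak was listed in any of the 4 libraries from 40000001 to 46000000. The median over that chromosome was 38 peaks per 1 Mb in KTS-minus replicate 1. Chromosomes 1 and 8 also held 1 Mb bins without a peak in any library. In each KTS-minus library, 11 of 2592 bins held no peak. Whether reads could be mapped to these empty bins was not tested. The missing peaks therefore do not show a lack of DNA or of WT1 there. Across 2592 bins of 1 Mb, which are not independent replicates, peak numbers of the KTS-minus libraries were ranked most alike (Spearman's rho 0.91). The rho was 0.72 for the M15 pair, 0.82 for M15 replicate 2 with either KTS-minus library, and 0.54 and 0.46 for M15 replicate 1 with KTS-minus replicates 1 and 2. In M15 replicate 1, 47.1% of bins held no peak, and such ties can lower each rho with that library. The values therefore do not show that M15 replicate 2 is spread more like KTS-minus than like M15 replicate 1.

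**Figure D4:**
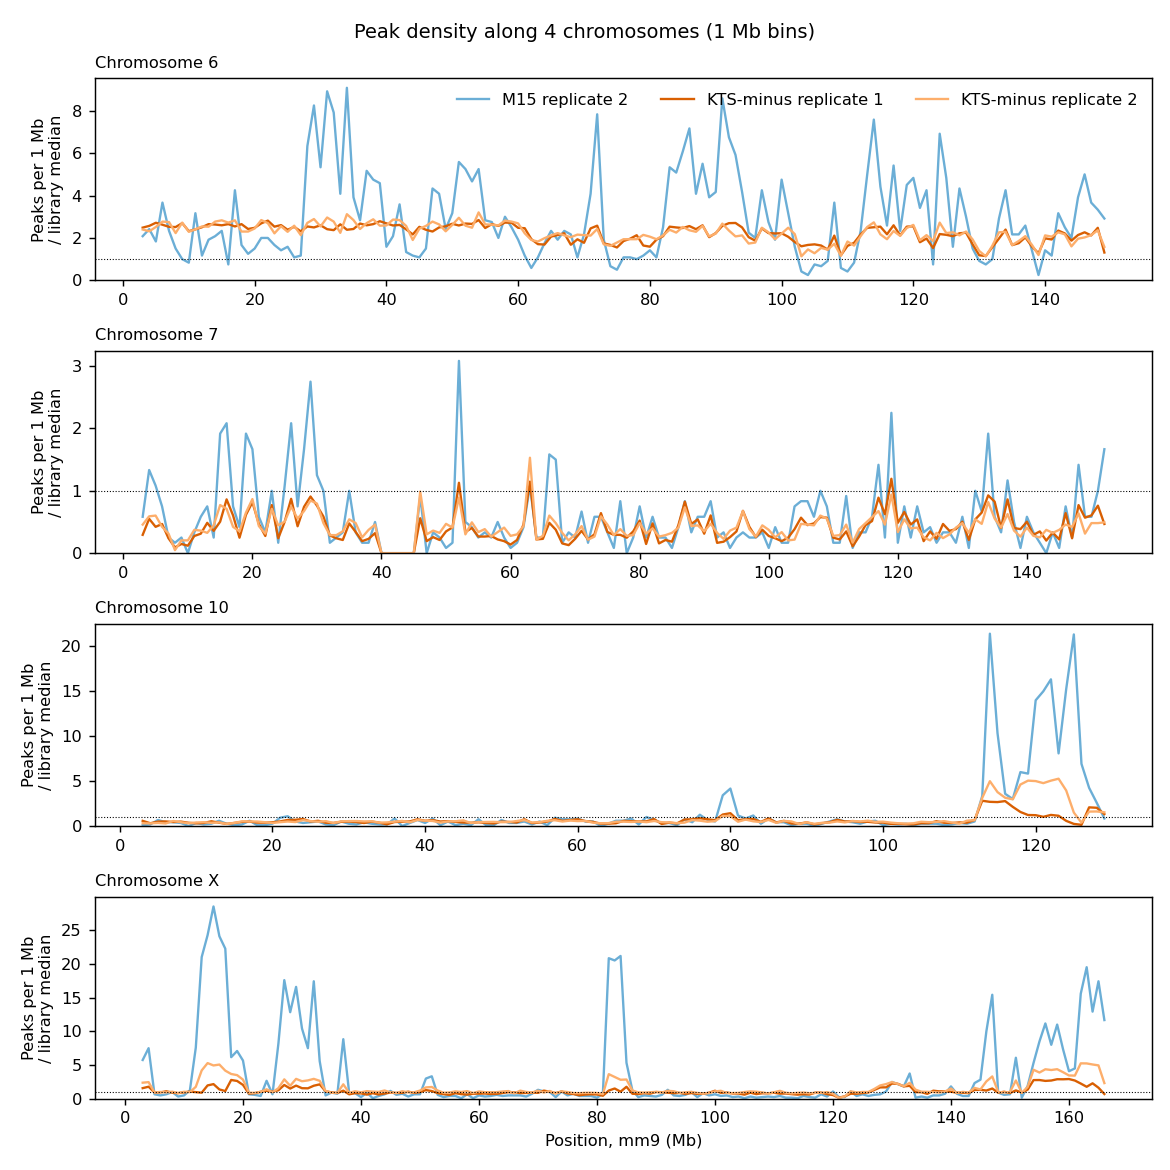
Peaks per 1 Mb bin divided by the library's median bin (linear axis) along chromosomes 6, 7, 10 and X in mm9, for M15 replicate 2 and both KTS-minus libraries; the dotted line marks the median, and M15 replicate 1 is left out because 47.1% of its bins hold no peak. In the chromosome 10 block peak number is 11.3 times the median in M15 replicate 2. It is 3.72 and 1.04 times the median in KTS-minus replicates 2 and 1, where peaks are wide. Chromosome 7 has no peak from 40000001 to 46000000, and whether reads could be mapped there was not tested.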

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

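The alternatives left 41 values within their limits, moved 20 and reversed 4. The limits were a factor of 1.5 for counts, 1 SD between replicates for shares and chromosome ratios, and 1 SD over the pairs of different lines for similarity. Results with a larger spread between replicates thus had wider limits, so the tally does not measure robustness. The limit for the chromosome X ratio was 1.34, and its fall from 2.2 to 1.07 in whole lists counted as within limits. Merging peaks within a line and leaving out dense blocks were added after seeing the data, as were leaving out single libraries for the chromosome ratios and keeping the list length without M15 replicate 1. The number of reproducible M15 regions was 2948 when each list was cut to the 50% of peaks with the highest total signal and 1869 when only the stretches of highest signal were overlapped. The KTS-minus number was 38057 and 8541 under these settings, and 26302 with a 50% reciprocal overlap. The shorter lists and narrower intervals account for lower counts by construction. The share of M15 regions with both KTS-minus libraries was 39.5% with a reciprocal overlap of 50%, 24.1% with the stretches of highest signal and 95.7% with the stronger peaks, and ranged from 42.3% (without M15 replicate 1) to 96.6% with single libraries left out. The replicate numbers are shared between lines, and nothing in the labels ties equal numbers together. At equal list length, pairs of equal number overlapped at 34.5% and 41.1% and the other pairs between lines at 38.8% and 38.6%. Within equal numbers (replicate block), 93.6% of M15 replicate 1 peaks overlapped KTS-minus replicate 1. For replicate 2 the share was 51.2%, and the mean of these shares was 72.4%. It counts peaks and asks for 1 KTS-minus library, so it is not the same measure as the share of regions with both. In the same setting the within-line excess in similarity was 12.1 percentage points. That excess ranged from -6.58 to 30.0 points with single libraries left out, negative without either M15 library (-3.70 without M15 replicate 1 when the list length was set again). The chromosome 10 ratio was 0.67 in whole lists, a reversal, and 1.69 when ranked by total signal. The chromosome 7 ratio was 0.80 and 0.34 under these settings, the chromosome 13 ratio was 0.40 when ranked by total signal, and the chromosome X ratio was 1.07 in whole lists and ranged from 1.54 to 3.85 with single libraries left out. The cause of these shifts was not tested. Counts of reproducible regions need both replicates, so leaving one out gives no value. The planned promoter, motif and gene list results had no mm9 annotation or sequence to rest on and were not run. Read depth is unknown, so a missing peak does not show a lack of binding.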

Other observations

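The comparison of additional peaks with M15 sites by excess overlap was chosen after its result was seen, and the dense blocks were defined after the data were examined. The bounds of the other tests were set before their values were known.

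The dense blocks were not limited to chromosomes 10 and X. Others lay on chromosome 15 from 76000001 to 80000000 and on chromosome 19 from 3000001 to 8000000 and from 42000001 to 48000000. In the chromosome 15 block, peaks covered 55.2% of the sequence in KTS-minus replicate 1, 19.8% in KTS-minus replicate 2, 16.0% in M15 replicate 2 and 4.34% in M15 replicate 1. Median max signal at regions held by all 4 libraries was near that elsewhere in this block (ratios of 0.94 to 1.09 over the 4 libraries) and somewhat higher in the chromosome 19 blocks (1.17 to 1.27).

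If most of the additional peaks in the longer KTS-minus lists were background coverage that passed the calling threshold, KTS-minus peaks away from any M15 peak would overlap between replicates little more than after a local shift. They did so 1.16 times as often in one direction (23.6% against 20.3%) and 1.18 times in the other (32.6% against 27.8%), below the limit of 1.2 set in advance. In these shares the overlapped list, too, was reduced to peaks without an M15 peak. When all peaks of the overlapped list counted, the ratios were 1.01 (24.1% against 23.8%) and 1.06 (36.9% against 34.8%). Against the other reading, sites of the same kind as the M15 sites seen in deeper libraries, additional peaks at equal max signal overlapped the other replicate 2.2 and 2.17 percentage points above a local shift, and peaks at M15 regions 45.9 and 31.4 points, so that the excess was at most 0.069 of that at M15 regions. The high overlap at M15 regions largely restates that 93.7% of them held a peak in both KTS-minus libraries, and the peaks were matched on max signal, not on width. An earlier form of this test compared ratios to the shifted share, which are capped at M15 regions because an overlap cannot exceed 100%. A small set of true KTS-minus sites among the additional peaks stays open, as does an effect of the editing on background, since line and library set are confounded and the IgG library was not analysed here.

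A candidate explanation for the higher covered share on chromosome 10 from 118000001 to 128000000 in all 4 libraries is a gain of DNA copies, which would raise all coverage, sites included. Regions held by all 4 libraries had a median max signal 1.95 and 1.64 times that elsewhere in KTS-minus replicates 1 and 2 (95% bootstrap intervals 1.64 to 2.14 and 1.42 to 1.83). In M15 replicates 1 and 2 it was 0.86 and 1.13 times (0.58 to 1.24 and 1.0 to 1.2). With regions of up to 10 kb only, 16 sites remained. The ratios were then 1.03 and 1.03 in M15 (upper ends 1.58 and 1.3) and 1.2 and 1.24 in KTS-minus (1.55 and 1.49). The prediction of at least 1.5 in every library was met in the KTS-minus libraries over all regions only. In M15 it was not met, and both M15 intervals over all regions ended below 1.5. A copy gain and wide WT1 occupancy cannot be told apart with peak lists alone. A biological difference between the lines remains untested.

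The chromosome X blocks passed the limit for dense blocks in M15 replicate 2 and both KTS-minus libraries. In M15 replicate 1 their signal per Mb was 1.57 to 3.21 times the median over bins with a peak. That median leaves out the 47.1% of M15 replicate 1 bins without a peak. A median over all bins would be lower and these ratios higher, so the contrast with M15 replicate 1 depends on this choice. A gain of copies in those 3 libraries could raise sites there, but the ratio of median max signal inside to elsewhere was 1.0 in M15 replicate 2 (0.93 to 1.13) and 1.32 and 1.31 in KTS-minus replicates 1 and 2, short of the 1.5 set in advance. A ratio under 1.2 in 2 of the 3 libraries, the bound set against a copy gain, was not reached over all sites either. With regions of up to 10 kb only, a limit that was not part of that bound, 33 sites remained and the ratios were 0.93, 1.05 and 1.06. The upper ends of the 95% bootstrap intervals were 1.13, 1.48 and 1.44 over all sites and 1.2, 1.14 and 1.31 with regions of up to 10 kb. All lay below 1.5. In M15 replicate 1, which did not pass the dense-block limit there, the ratio was 0.77 (0.5 to 0.92) over all sites. With regions of up to 10 kb it was 1.0 (0.83 to 1.33). The ratio expected without a gain is thus not known to be 1, and the 10 kb limit drops the widest regions. The values therefore do not decide on a gain of 1.5 times in M15 replicate 2 and both KTS-minus libraries. A smaller gain stays open too, because 2 of the intervals at regions of up to 10 kb reached 1.2 or more. Whether the M15 replicates came from different stocks of the line was not tested.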
